A study of Mus musculus with 19 samples.

How the data were processed

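RNA was measured on 19 Affymetrix Mouse Genome 430 2.0 arrays, in 9 groups of purified mouse cortical projection neurons. Per the labels, callosal projection neurons (CPN) and corticospinal motor neurons (CSMN) were collected at E18, P3, P6 and P14 and corticotectal projection neurons (CTPN) at P14. Each group has 2 arrays, except CSMN at P3 with 3, and the labels call replicates independent biological collections. Per the labels, RNA was purified with a StrataPrep kit, amplified in 2 rounds of in vitro transcription and labelled with biotin. The deposited values are log2 expression per probe set, which the authors made with RMA (background correction, quantile normalization and summary per probe set; no software version is given). The values ran from 3.17 to 14.4 and were used as deposited, and all columns of values were used.

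The table holds 45101 probe sets, of which 64 are array controls, 34945 carry 1 gene symbol, 932 several and 9160 none. A gene was represented by its brightest probe set, chosen by the mean over all arrays among probe sets with 1 symbol, which gave 18193 genes. Symbols were checked against RefSeq entries by gene identifier, found for 34741 probe sets, and 0 symbols changed.

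One limma model of 9 group means was fitted to all arrays (10 residual and 4.46 prior degrees of freedom), with moderated two-sided tests and Benjamini-Hochberg adjusted p under 0.05 over all genes. The comparisons were CSMN against CPN as the mean of 4 stages and at each stage, P14 against E18 in CPN and in CSMN, the difference between these (the interaction), each step between stages as the mean of both types, and CTPN against CSMN and against CPN at P14. Standard errors are those of the model, with spread shared over groups since most have 2 arrays, which limits the precision. The model was tested on simulated data with 100 of 18193 genes changed at each size: for a log2 change of 1 it recovered 94% in the mean of 4 stages, 31% between P14 and E18 in CPN, 32% between CSMN and CPN at P14 and 32% between CTPN and CSMN. For a change of 2 it recovered 100%, 91%, 94% and 95%, with 5.37%, 3.17%, 2.33% and 5.93% of all calls false. The real spread differed by group, so these may not hold.

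In all 30 gene lists with 688 genes, of which 630 were measured, were fixed. They cover projection neuron identity, cortical layers, areas, axons, synapses, channels, metabolism, motor neuron disease, sex-linked genes and markers of other cell types. Each list was tested in 6 comparisons with camera, with a preset correlation between genes of 0.01 and again with an estimated one, adjusted over the lists of a comparison. Of 180 tests, 70 passed with the preset correlation, and 19 of these also passed with the estimated one. The p for the estimated correlation is given beside lists that passed with the preset one alone. Which lists are described in which comparison was chosen after the list results had been seen.

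Genes were named by a rule. For the mean of 4 stages, both comparisons of P14 with E18 and both comparisons with CTPN, it takes the 8 largest differences per direction past the test. For the interaction and single stages it takes 5, passing over symbols that are clone or model numbers. For each list described it takes up to 4 members past the test with the largest difference. The rule also allowed up to 2 well known members that did not pass, but no member was named on that ground. Bcl11b, Fezf2, Crym, Lmo4 and Cux2 are always named between types, and 1 further item of this rule is not reported here. The groups, comparisons, lists, this rule and all settings below except the last were fixed before the data were examined.

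The results were recomputed with quantile and cyclic loess normalization between arrays, the genes above the median brightness, the mean of all probe sets of a gene, leaving out probe sets marked for cross-hybridization, an intensity trend in the spread, array weights, a minimum absolute log2 difference of 1, a model of the groups compared only, a block for the replicate number, and leaving out each array in turn. Not using the E18 arrays in a comparison, with P3 in their place where a first stage was needed, was added after the data were seen. Genes called in CSMN and CTPN against the same CPN arrays were compared with 100 simulations of groups without a difference. Splits of the arrays into other groups of the same sizes were counted, at most 100 per comparison. Probe sets without a single symbol were left out of the gene tests, and their count is given among the additional observations. Analyses used R 4.3.3 with limma 3.58.1, and figures used Python 3.11.15 with matplotlib 3.10.9.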

Results

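Gene expression was measured on 19 Affymetrix Mouse Genome 430 2.0 arrays in projection neurons of the cerebral cortex of C57BL/6 mice. The neurons had been marked with fluorescent microspheres carried back along their axons and then isolated by fluorescence-activated cell sorting. Corticospinal motor neurons (CSMN) send axons to the spinal cord, callosal projection neurons (CPN) connect the hemispheres, and corticotectal projection neurons (CTPN) reach the tectum of the midbrain. CSMN and CPN were collected at embryonic day 18 (E18) and at postnatal days 3, 6 and 14 (P3, P6 and P14), and CTPN at P14. Each group held 2 arrays, except CSMN at P3 with 3. The labels name the sensorimotor cortex for CSMN and CPN and the visual cortex for CTPN, so neuron type and cortical area changed together in every comparison with CTPN. Array medians lay between 6.42 and 6.62 and 75th percentiles between 7.85 and 8.26 on the log2 scale, and the number of arrays limits the precision. The values carry no detection calls, so the size of a difference also depends on background where a group lies below the array medians, and folds are given only where all arrays compared lay above 6.62. Differences below are on the log2 scale, given ± the standard error (SE) of the shared model.

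The first question was which genes distinguish CSMN from CPN across the 4 stages. Transcription factors of subcerebral identity were higher in CSMN: Bcl11b by 7.73-fold (2.95 ± 0.20, adjusted p = 5.83e-07) and Fezf2 by 3.80-fold (1.92 ± 0.14, adjusted p = 7.32e-07). Crym, a thyroid hormone binding protein, was higher by 3.60 ± 0.23, Npr3, the clearance receptor of natriuretic peptides, by 3.65 ± 0.20 and Tcerg1l 9.16-fold (SE 0.12 on the log2 scale). In the other direction the upper-layer transcription factor Cux2 (-3.22 ± 0.34, adjusted p = 2.89e-05) and the LIM homeobox gene Lhx2 (-3.25 ± 0.29) were lower in CSMN. So were the netrin receptor Dcc (-3.13 ± 0.18) and the related receptor Unc5d (-3.04 ± 0.14). Lmo4, a transcriptional cofactor, was 2.97-fold lower (-1.57 ± 0.16, adjusted p = 2.77e-05). The other genes with the largest differences were Ermn (4.65 ± 0.24), Ankrd34b (2.87 ± 0.19), Oma1 (2.61 ± 0.12) and Cd55 (2.56 ± 0.27), higher in CSMN, and Lpl (-3.12 ± 0.22), Adamts3 (-3.02 ± 0.21), Itgb8 (-2.90 ± 0.23) and Cryab (-2.88 ± 0.30), lower. At each stage every CSMN array lay beyond every CPN array for all of these genes except Lmo4, whose groups overlapped at E18.

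**Figure D1:**
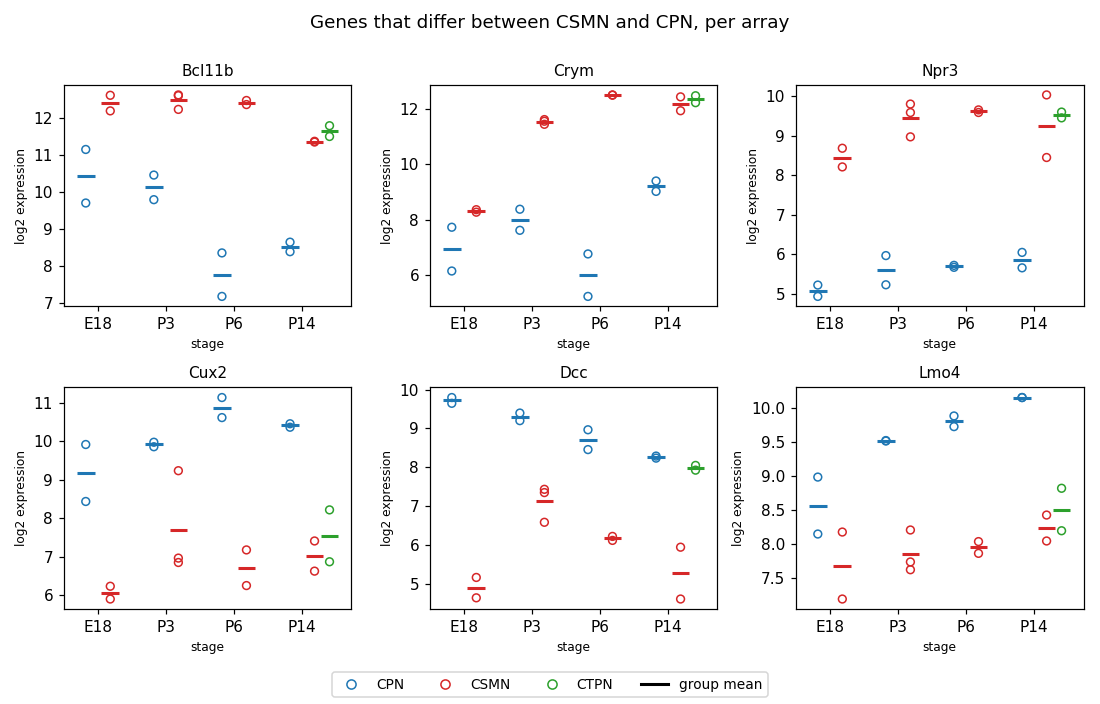
Log2 expression of 6 genes in each array, by stage on the horizontal axis, with an open circle per array (blue CPN, red CSMN, green CTPN) and a bar at each group mean. Bcl11b, Crym and Npr3 were higher, and Cux2 and Dcc lower, in every CSMN array than in every CPN array of the same stage, while Lmo4 overlapped at E18 and was lower in CSMN at P3, P6 and P14.

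Genes that earlier array screens named for these neurons separated the types. Of 15 genes named for corticospinal or subcerebral neurons, 13 were higher in CSMN and 2 did not pass, with Pcp4 at 1.86 ± 0.16 among the former (13 higher and 1 lower adjusted over the list alone, median 1.10, camera adjusted p = 7.24e-18). Of 17 genes named for callosal neurons, 16 were lower in CSMN and 1 did not pass (16 lower adjusted over the list alone, median -1.80, camera adjusted p = 4.66e-28). Lower members included Epha3 (-2.54 ± 0.21), Plxnd1 (-2.48 ± 0.16) and Btg1 (-2.34 ± 0.26). Both screen lists were chosen partly on samples of this kind, by the same study line, and are not independent evidence of their direction. Among 17 other layer V and subcerebral markers, 12 were higher, including Npr3, Tcerg1l, Nefh (1.54 ± 0.23) and Tox (1.15 ± 0.14), and 5 did not pass (13 higher adjusted over the list alone, median 0.90, adjusted p = 6.75e-13). Upper-layer markers went the other way, with 9 of 18 lower, 1 higher and 8 not past the test (9 lower and 1 higher adjusted over the list alone, median -0.51, adjusted p = 1.46e-07). Besides Cux2, Lhx2 and Unc5d these included the cadherin Cdh10 (-1.83 ± 0.13).

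Genes that pattern cortical areas were lower on balance, with 7 of 18 lower, 2 higher and 9 not past the test (8 lower and 2 higher adjusted over the list alone, median -0.37, adjusted p = 7.04e-06). Those lower included the transcription factor Nr2f1 (-2.65 ± 0.20) and the ephrin receptor genes Epha3 and Epha4 (Epha4 -2.19 ± 0.18). Among 21 neurofilament and axonal transport genes, 5 were higher and 16 did not pass (6 higher and 1 lower adjusted over the list alone, median 0.18, adjusted p = 0.000592, or 0.269 with an estimated correlation). The neurofilament subunit genes Nefl (1.76 ± 0.13), Nefm (1.46 ± 0.13) and Nefh and the tubulin gene Tuba4a (1.11 ± 0.09) were among the 5. Axon growth and guidance genes went both ways, 7 higher such as Ephb1 (1.19 ± 0.13) and 7 lower such as Dcc, with 34 not past the test (9 higher and 10 lower adjusted over the list alone), a median of 0.02, a mean of -0.12 and an adjusted p of 0.402. Cadherins and protocadherins also went both ways, with 4 of 25 higher, among them Cdh13 (1.11 ± 0.21), 6 lower, among them Pcdh11x (-1.20 ± 0.20) and Cdh9 (-1.02 ± 0.17), and 15 not past the test (4 higher and 8 lower adjusted over the list alone, median -0.08, adjusted p = 0.0682). Among 27 early response and stress genes, 5 were lower, including Fos (-2.02 ± 0.25), Fosl2 (-1.43 ± 0.21), Egr1 (-1.04 ± 0.22) and Ier5 (-0.76 ± 0.20), 2 higher and 20 not past the test (7 lower and 2 higher adjusted over the list alone, median -0.17, adjusted p = 0.00888, or 0.568 with an estimated correlation). Without E18 the early response list did not pass (median -0.18, adjusted p = 0.0622), nor did Egr1 (-0.36) and Ier5 (-0.42), while Fos (-1.38) and Fosl2 (-1.14) did. The early response list also did not pass without CSMN P14 replicate 2 (median -0.08) and had a median of -0.38 without replicate 1. The neurofilament list did not pass without replicate 1 (median 0.17) and had a median of 0.33 without replicate 2. The cadherin list passed without CPN E18 replicate 1 (-0.08), CPN P6 replicate 1 (-0.17) or CSMN E18 replicate 2 (-0.09), and the axon growth median was 0.14 without CSMN P14 replicate 2.

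Dividing-cell and progenitor transcripts were also lower in CSMN over the 4 stages, and neither list passed without E18. Of 27 cell cycle genes, 17 were lower and 10 did not pass (20 lower adjusted over the list alone, median -0.59, adjusted p = 4.21e-17). Lower members included Mcm6 (-1.27 ± 0.19), the proliferation marker Mki67 (-1.09 ± 0.12), Top2a (-1.02 ± 0.14) and Cenpf (-0.94 ± 0.11). Of 19 cortical progenitor genes, 11 were lower and 8 did not pass (14 lower adjusted over the list alone, median -0.74, adjusted p = 6.75e-13). Lower members included Fabp7 (-2.63 ± 0.35), Sox2 (-2.18 ± 0.36), Tnc (-1.61 ± 0.17) and Eomes (-1.48 ± 0.10). Astrocyte markers were lower for 10 of 20, higher for 1 and not past the test for 9 (12 lower and 4 higher adjusted over the list alone, median -0.48, adjusted p = 6.17e-05, or 0.157 with an estimated correlation). Lower members included Aldoc (-1.71 ± 0.25), Gja1 (-1.64 ± 0.36), Aldh1l1 (-1.45 ± 0.16) and Slc1a2 (-1.36 ± 0.17). With P3, P6 and P14 alone the list medians were 0.08, -0.09 and 0.09 (adjusted p = 0.7, 0.142 and 0.977), and Mki67 (0.10) and Top2a (0.28) changed sign. Of the members named, Mcm6 (-0.87, adjusted p = 0.0389) and Slc1a2 (-0.94, adjusted p = 0.0112) still passed there and the others did not. Young-neuron transcription factors were lower for 9 of 23, higher for 3 and not past the test for 11 (13 lower and 4 higher adjusted over the list alone, median -0.34, adjusted p = 9.09e-06, or 0.157 with an estimated correlation). Cited2 (-2.29 ± 0.24) and Zbtb20 (-1.73 ± 0.14) kept a difference without E18 (-1.64 and -1.01), and Neurog2 (-1.56 ± 0.09) and Insm1 (-1.53 ± 0.21) did not (-0.11 and -0.28). Interneuron markers were lower for 3 of 18 (Npy -1.57 ± 0.25, Slc32a1 -0.88 ± 0.24 and Lhx6 -0.72 ± 0.17) and not past the test for 15 (7 lower adjusted over the list alone, median -0.12, adjusted p = 0.00424, or 0.389 with an estimated correlation), and the list did not pass without CPN E18 replicate 2 (median -0.12) or CSMN P14 replicate 1 (-0.12). Its median was -0.07 without CPN P6 replicate 2 and -0.05 without CPN P14 replicate 1. Without E18 the list (-0.20, preset correlation alone) and Npy passed, and Slc32a1 and Lhx6 did not.

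In all, 1509 of 18193 genes passed the limma test, 538 higher and 971 lower in CSMN, of which 373 differed at least 2-fold. Without the E18 arrays in the contrast 747 genes passed, 379 higher and 368 lower, and 644 of them were called in the same direction with E18. Leaving out CSMN P14 replicate 2 gave 2123 genes, 1093 higher, and leaving out CSMN P14 replicate 1 gave 5262.

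Taken stage by stage, the type difference covered 2350 genes at E18 (724 higher and 1626 lower in CSMN), 159 at P3 (91 and 68), 195 at P6 (122 and 73) and 253 at P14 (81 and 172). At E18 the transcripts lowest in CSMN relative to CPN were those of radial glia and intermediate progenitors. They included Fabp7 (-8.35 ± 0.72), Sox2 (-7.22 ± 0.73), the gap junction gene Gja1 (-6.26 ± 0.73), the proneural factor Neurog2 (-5.91 ± 0.18) and Eomes (-5.79 ± 0.20). In CSMN at E18 these 5 genes lay between 4.23 (Gja1) and 5.89 (Fabp7), below the array medians, so the size of their differences depends on background. The cell cycle list's median was 8.98 and 9.13 in the CPN E18 arrays and between 6.11 and 6.73 in the others. The largest increases at E18 were those of Ermn (6.10 ± 0.50), Tcerg1l (4.18 ± 0.25), Npr3 (3.38 ± 0.41), Far2 (3.17 ± 0.51) and Galntl6 (3.10 ± 0.38). Bcl11b (1.97 ± 0.42), Fezf2 (1.33 ± 0.28) and Cux2 (-3.10 ± 0.69) also passed at E18, whereas Crym (1.38 ± 0.47, adjusted p = 0.0704) and Lmo4 (-0.88 ± 0.33, adjusted p = 0.0968) did not. Bcl11b was 1.25 without CPN E18 replicate 1.

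At the 3 postnatal stages the genes with the largest differences were mostly those of the 4-stage mean. At P3, Ermn (5.70 ± 0.45), Ankrd34b (4.19 ± 0.36), Npr3 (3.87 ± 0.38), Tcerg1l (3.55 ± 0.23) and Crym (3.54 ± 0.43) were higher in CSMN, and Klhl4 (-3.60 ± 0.71), Lhx2 (-3.53 ± 0.54), Cryab (-3.29 ± 0.55), the caveolin gene Cav1 (-3.24 ± 0.42) and Lpl (-3.19 ± 0.40) lower. Bcl11b (2.36 ± 0.38), Fezf2 (1.92 ± 0.26) and Lmo4 (-1.66 ± 0.30) passed at P3, and Cux2 did not (-2.23 ± 0.63, adjusted p = 0.155). At P6, Crym (6.50 ± 0.47) had the largest increase, followed by Ermn (5.07 ± 0.50), Bcl11b (4.64 ± 0.42), Ankrd34b (4.58 ± 0.39) and Npr3 (3.94 ± 0.41). Cux2 (-4.16 ± 0.69), Lpl (-3.69 ± 0.44), Adamts3 (-3.61 ± 0.42), Grp, which encodes gastrin-releasing peptide (-3.59 ± 0.66), and Cpne4 (-3.38 ± 0.45) had the largest decreases at P6. Fezf2 (2.59 ± 0.28) and Lmo4 (-1.85 ± 0.33) passed as well. At P14 the largest increases were in Npr3 (3.40 ± 0.41), Cdc25c (3.15 ± 0.42), Nefh (3.09 ± 0.47), Crym (2.97 ± 0.47) and Bcl11b (2.84 ± 0.42), and the largest decreases in Gpr6 (-3.80 ± 0.39), Cux2 (-3.38 ± 0.69), Unc5d (-3.27 ± 0.29), the troponin gene Tnnc1 (-3.24 ± 0.30) and Strip2 (-3.14 ± 0.25). Fezf2 (1.86 ± 0.28) and Lmo4 (-1.91 ± 0.33) again passed.

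A core of 20 genes was called in the same direction at all 4 stages. The 8 higher in CSMN were Bcl11b, Fezf2, Ifi27, Ldb2, Npr3, Oma1, Rgma and Tcerg1l. The 12 lower were Adamts3, Cdh10, Dcc, Gria4, Hs3st1, Limch1, Lpl, Nr2f1, Plxnd1, Ptprk, Slc17a6, which encodes a vesicular glutamate transporter, and Unc5d. Another 2182 genes were called at E18 and at no later stage, and 438 at P3, P6 or P14, 270 of them not at E18. The 20 are listed as a set outside the rule for named genes, chosen after their values were seen. With array weights, and with a model of the groups compared alone, 0 genes were called at all 4 stages (limma).

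The stage counts moved with single arrays. E18 gave 1121 genes without CPN E18 replicate 1. P3 gave 35 and 29 without CPN P3 replicates 1 and 2, and 85 and 70 without CSMN P3 replicates 1 and 2. P6 gave 88 and 117 without CPN P6 replicates 1 and 2, and 53 and 66 without CSMN P6 replicates 1 and 2. E18, P3 and P6 gave 4253, 341 and 383 without either CSMN P14 array, which enters them only through the shared spread. P14 gave 40 and 79 without CPN P14 replicates 1 and 2, 6256 without CSMN P14 replicate 1, and 325 (229 higher, 96 lower) without replicate 2, of which 150 were called in the same direction with both. With array weights P3 gave more genes than E18, and P14 gave 2, or 0 with a model of the groups compared alone. The 20 genes of all 4 stages became 8 and 9 without CPN P3 replicates 1 and 2, 7 without either CPN P14 array, and 45 and 40 without CSMN P14 replicates 1 and 2. The share of called genes higher in CSMN also moved: 30.8% at E18 against 45.9% after quantile normalization, and 57.2% at P3 and 32.0% at P14 against 46.2% and 44.2% after cyclic loess.

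**Figure D2:**
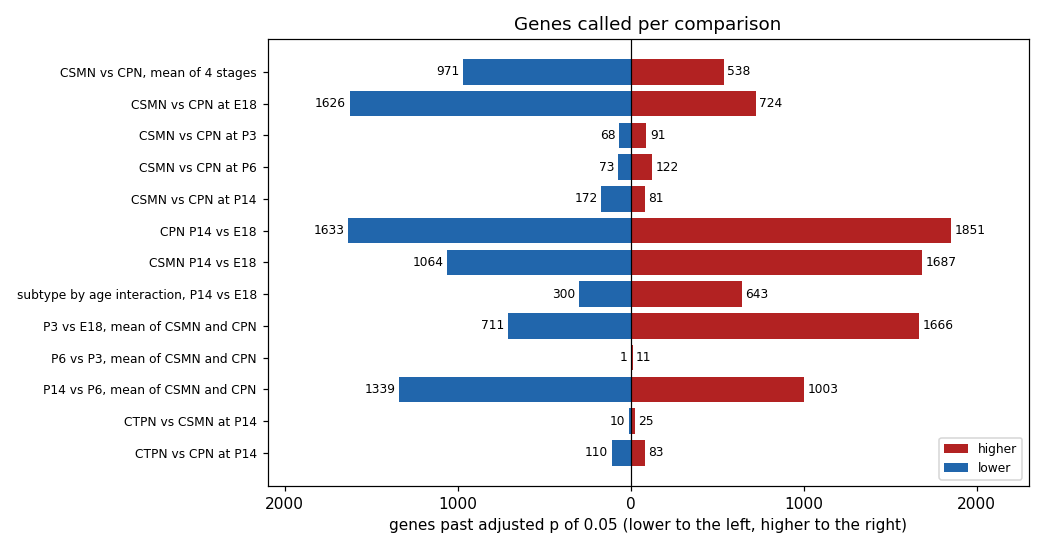
Number of genes past adjusted p 0.05 per comparison, higher to the right (red) and lower to the left (blue) of 0 (horizontal axis). The type difference held 2350, 159, 195 and 253 genes at E18, P3, P6 and P14, but most at P3 with array weights.

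The next question was how each type changed between E18 and P14. In CPN lists of synaptic and channel genes leaned up with the preset correlation. Of 26 presynaptic genes, 23 rose and 3 did not pass (24 higher adjusted over the list alone, median 2.13, adjusted p = 9.35e-21). Rises included the endocytic GTPase Dnm1 (4.53 ± 0.50), Syt13 (4.12 ± 0.32), Syp (3.88 ± 0.37) and Snap25 (3.70 ± 0.29). Of 32 glutamate receptor and postsynaptic density genes, 17 rose and 15 did not pass (18 higher adjusted over the list alone, median 1.08, adjusted p = 4.47e-10, or 0.0741 with an estimated correlation). Rises included Ddn (4.14 ± 0.32), the kinase Camk2a (3.40 ± 0.27), the activity-regulated Arc (3.29 ± 0.33) and Nrgn (2.86 ± 0.32). GABA receptor and chloride transport genes rose for 11 of 13, fell for 1 and did not pass for 1 (12 higher and 1 lower adjusted over the list alone, median 1.97, adjusted p = 4.48e-08, or 0.12 with an estimated correlation). Rises included Gabrd (4.21 ± 0.38), the chloride extruder Slc12a5 (3.69 ± 0.27), Gabra4 (3.43 ± 0.34) and Gabra3 (2.20 ± 0.38). Of 36 sodium, potassium and HCN channel genes, 20 rose and 16 did not pass (21 higher adjusted over the list alone, median 1.54, adjusted p = 4.88e-13). Rises included Kcnf1 (4.85 ± 0.43), Kcnip4 (4.24 ± 0.38), Kcns2 (3.56 ± 0.40) and Kcnv1 (3.10 ± 0.33). Calcium-binding and calcium-signalling genes rose for 21 of 30 and did not pass for 9 (24 higher and 1 lower adjusted over the list alone, median 1.73, adjusted p = 3.24e-15). Rises included Vsnl1 (4.81 ± 0.32), Calb1 (4.79 ± 0.52), Hpca (4.15 ± 0.44) and Cacna2d3 (4.02 ± 0.29).

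Lists of energy metabolism and early response genes leaned up in CPN with the preset correlation. Glycolysis genes rose for 9 of 15, fell for 1 (Aldoc, -3.75 ± 0.51, also an astrocyte marker) and did not pass for 5 (10 higher and 1 lower adjusted over the list alone, median 0.86, adjusted p = 0.000375, or 0.318 with an estimated correlation). Eno2 (4.38 ± 0.38), Slc2a3 (2.44 ± 0.25) and Aldoa (1.96 ± 0.30) were among the risers. Oxidative phosphorylation genes rose for 7 of 41 and did not pass for 34 (9 higher adjusted over the list alone, median 0.50, adjusted p = 6.70e-06, or 0.401 with an estimated correlation), with Ndufs3 (1.09 ± 0.20), Ndufa4 (0.99 ± 0.28), Ndufb8 (0.96 ± 0.30) and Ndufs1 (0.78 ± 0.26) having the largest rises. Early response and stress genes rose for 8 of 27, fell for 1 and did not pass for 18 (8 higher and 1 lower adjusted over the list alone, median 0.40, adjusted p = 0.00174, or 0.396 with an estimated correlation). Rises included the activity-regulated factors Egr3 (5.95 ± 0.50), Egr2 (3.44 ± 0.49) and Junb (3.02 ± 0.38). The other largest rises were those of Slc24a2 (5.76 ± 0.32), Rasgrp1 (5.68 ± 0.23), Cracdl (5.60 ± 0.32), Lamp5 (5.54 ± 0.31), Lin7b (5.50 ± 0.19), Mal2 (5.41 ± 0.33) and Icam5 (5.26 ± 0.28).

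What fell in CPN was led by transcripts of progenitors and dividing cells, which stood out in the CPN E18 arrays. Cell cycle genes fell for 24 of 27 and did not pass for 3 (25 lower adjusted over the list alone, median -2.52, adjusted p = 2.33e-27), with Top2a (-5.42 ± 0.29), Mki67 (-5.41 ± 0.24), Rrm2 (-4.13 ± 0.38) and Cdk1 (-3.91 ± 0.28) falling most. Progenitor genes fell for 15 of 19 and did not pass for 4 (16 lower adjusted over the list alone, median -3.33, adjusted p = 4.01e-19), with the intermediate filament gene Vim (-6.08 ± 0.37), Sox2 (-6.03 ± 0.73), Eomes (-5.85 ± 0.20) and Fabp7 (-5.55 ± 0.72) falling most. Young-neuron transcription factors fell for 13 of 23 and did not pass for 10 (15 lower adjusted over the list alone, median -1.23, adjusted p = 1.78e-11). Decreases included Neurog2 (-6.31 ± 0.18), Sox11 (-5.46 ± 0.22), Insm1 (-5.10 ± 0.44) and Sox4 (-3.51 ± 0.29). Rlbp1 (-5.96 ± 0.27) and F2r (-5.61 ± 0.43) completed the largest decreases. Astrocyte markers fell for 10 of 20, rose for 2 and did not pass for 8 (10 lower and 3 higher adjusted over the list alone, median -0.87, adjusted p = 0.00103, or 0.273 with an estimated correlation). Decreases included Mlc1 (-4.88 ± 0.34), Slc1a3 (-4.79 ± 0.34) and Gja1 (-3.96 ± 0.73). Microglia and macrophage markers fell for 7 of 25 and did not pass for 18 (11 lower adjusted over the list alone, median -0.64, adjusted p = 0.000102, or 0.401 with an estimated correlation). Decreases included Ly86 (-1.91 ± 0.41), Ccl3 (-1.76 ± 0.44), Tyrobp (-1.43 ± 0.41) and Fcgr3 (-1.14 ± 0.30). Ccl3 was -0.74 and -2.78 without CPN E18 replicates 1 and 2. Axon growth and guidance genes fell for 11 of 48, rose for 4 and did not pass for 33 (11 lower and 4 higher adjusted over the list alone, median -0.29, adjusted p = 0.00955, or 0.579 with an estimated correlation), with Dcx (-2.85 ± 0.46), Robo1 (-2.67 ± 0.55) and Dpysl3 (-2.08 ± 0.46) lower and Sema3e (2.16 ± 0.47) higher. The axon growth median was -0.47 without CPN E18 replicate 2.

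**Figure D3:**
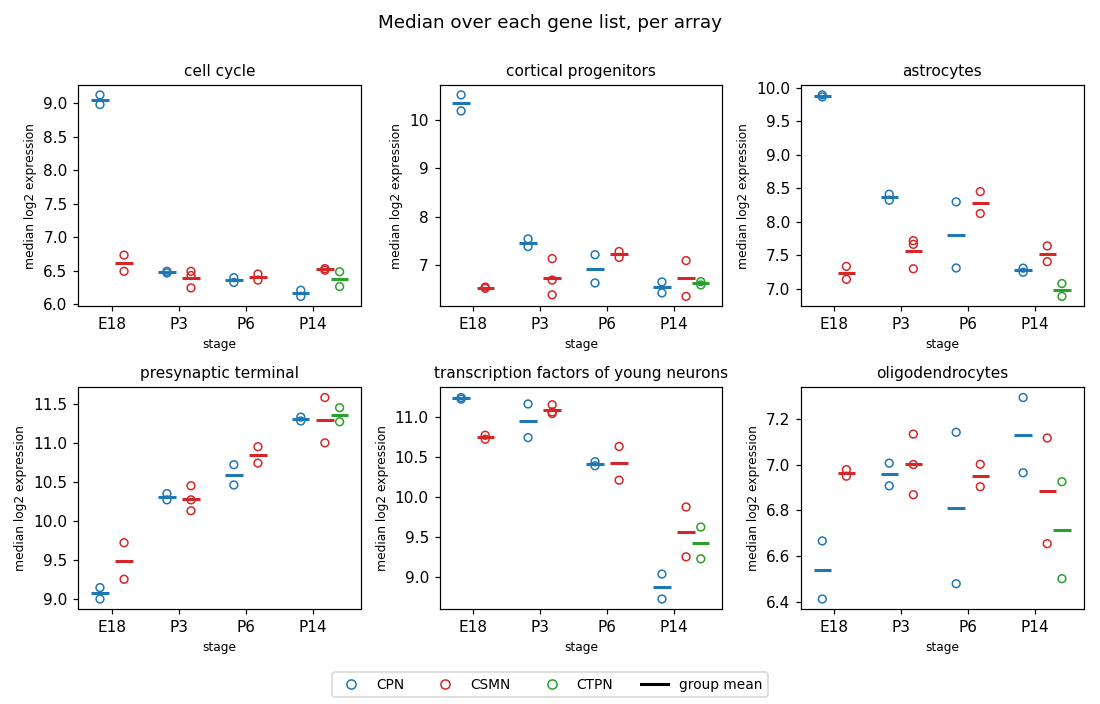
Median log2 expression over the members of 6 gene lists in each array, by stage on the horizontal axis, with an open circle per array (blue CPN, red CSMN, green CTPN) and a bar at each group mean. Cell cycle medians were 8.98 and 9.13 in the CPN E18 arrays and at most 6.73 in the others, and presynaptic medians were higher at P14 than at E18 in both types.

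CPN changed in 3484 genes between E18 and P14, 1851 higher and 1633 lower. Against P3 in place of E18, 1480 genes passed, 852 higher, 1148 of them in the same direction as against E18. In that comparison the presynaptic median was 1.03, the young-neuron factor median -1.0, the cell cycle median -0.14 and the progenitor median -0.37, and Eomes (0.23) changed sign. Glutamate receptor and postsynaptic density genes (median 0.29, 3 of 32 higher, adjusted p = 0.0547) and astrocyte markers (-0.13, adjusted p = 0.327) did not pass there, and GABA receptor genes passed with 3 of 13 higher (median 0.39, adjusted p = 0.0216, or 0.544 with an estimated correlation). Of 63 genes named, 18 did not pass there: Ndufs3, Ndufa4, Ndufb8 and Ndufs1, with 0 of 41 oxidative phosphorylation genes past the test in limma, Ly86, Ccl3, Tyrobp and Fcgr3, with 1 of 25 microglia markers, and Aldoc, Cdk1, Ddn, Eomes, Gabra3, Insm1, Kcns2, Neurog2, Nrgn and Sema3e. Without CPN P14 replicates 1 and 2 the count was 2137 and 2212.

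In CSMN the same synaptic and channel lists leaned up with the preset correlation. Presynaptic genes rose for 20 of 26 and did not pass for 6 (23 higher adjusted over the list alone, median 1.51, adjusted p = 2.94e-18, or 0.0592 with an estimated correlation). Rises included Sv2b (3.70 ± 0.22), Syt13 (3.52 ± 0.32), Dnm1 (3.48 ± 0.50) and Syp (3.40 ± 0.37). Glutamate receptor and postsynaptic density genes rose for 11 of 32, fell for 1 and did not pass for 20 (12 higher and 1 lower adjusted over the list alone, median 0.56, adjusted p = 2.82e-05, or 0.23 with an estimated correlation). Rises included the AMPA receptor subunits Gria3 (4.88 ± 0.48) and Gria1 (3.76 ± 0.38), Nrgn (3.16 ± 0.32) and Ddn (3.00 ± 0.32). GABA receptor and chloride transport genes rose for 6 of 13 and did not pass for 7 (6 higher adjusted over the list alone, median 0.90, adjusted p = 7.18e-06, or 0.227 with an estimated correlation). Rises included Gabra4 (5.09 ± 0.34), Slc12a5 (3.15 ± 0.27), Gabra2 (2.96 ± 0.43, but -0.15 against P3) and Gabrb1 (2.43 ± 0.41). Sodium, potassium and HCN channel genes rose for 17 of 36 and did not pass for 19 (22 higher and 1 lower adjusted over the list alone, median 0.95, adjusted p = 1.70e-09, or 0.111 with an estimated correlation). Rises included Kcnf1 (4.73 ± 0.43), Kcnip4 (3.92 ± 0.38), Scn1a (2.98 ± 0.56) and Scn2b (2.73 ± 0.30). Calcium genes rose for 16 of 30 and did not pass for 14 (17 higher adjusted over the list alone, median 1.30, adjusted p = 2.60e-09, or 0.0592 with an estimated correlation). Rises included Vsnl1 (4.36 ± 0.32), Cacna2d3 (4.33 ± 0.29), Rcan2 (2.99 ± 0.28) and Cacnb4 (2.49 ± 0.29).

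Lists of layer V and metabolic genes leaned up in CSMN with the preset correlation. Genes of the corticospinal screens rose for 8 of 15, fell for 2 and did not pass for 5 (8 higher and 3 lower adjusted over the list alone, which is not independent evidence, median 1.55, adjusted p = 0.000847, or 0.164 with an estimated correlation). Rises included Igfbp4 (4.69 ± 0.20), Crym (3.87 ± 0.47), Cdh22 (2.37 ± 0.29) and Opn3 (2.14 ± 0.21). Layer V and subcerebral markers rose for 8 of 17, fell for 1 and did not pass for 8 (8 higher and 1 lower adjusted over the list alone, median 0.99, adjusted p = 7.78e-05, or 0.164 with an estimated correlation). Rises included Nefh (4.67 ± 0.47), Lypd1 (4.18 ± 0.34), Parm1 (3.51 ± 0.44) and Chst8 (2.70 ± 0.55, but 1.76 without CSMN P14 replicate 1). This list rose in CPN too, for 7 of 17 with 10 not past the test (8 higher and 1 lower adjusted over the list alone, median 0.78, adjusted p = 0.0056, or 0.29 with an estimated correlation). Its interaction did not pass (median 0.89, adjusted p = 0.0836), except without CSMN P14 replicate 2 (median 1.4, adjusted p = 0.0119, or 0.132 with an estimated correlation). Oxidative phosphorylation genes rose for 19 of 41 and did not pass for 22 (35 higher adjusted over the list alone, median 0.77, adjusted p = 2.24e-11, or 0.236 with an estimated correlation). Of these, Uqcrq (1.55 ± 0.39) had a difference of -0.05 without probe sets marked for cross-hybridization and of 2.41 and 0.69 without CSMN E18 replicates 1 and 2, and Atp5d (1.33 ± 0.28), Ndufa5 (1.23 ± 0.25) and Ndufs3 (1.16 ± 0.20) followed. Glycolysis genes rose for 8 of 15 and did not pass for 7 (12 higher adjusted over the list alone, median 1.26, adjusted p = 4.10e-09, or 0.164 with an estimated correlation). Rises included Eno2 (3.40 ± 0.38), Ldhb (2.48 ± 0.18), Aldoa (1.96 ± 0.30) and Slc2a3 (1.91 ± 0.25).

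With the preset correlation the early response, astrocyte and microglia lists leaned up in CSMN, and the lists of young-neuron factors and sterol synthesis leaned down. Early response and stress genes rose for 13 of 27, fell for 1 and did not pass for 13 (16 higher and 1 lower adjusted over the list alone, median 1.09, adjusted p = 2.62e-07, or 0.19 with an estimated correlation). Rises included Egr1 (4.95 ± 0.45), Egr3 (4.37 ± 0.50), Fos (3.06 ± 0.51) and Egr4 (2.36 ± 0.32). Astrocyte markers rose for 6 of 20, fell for 1 and did not pass for 13 (7 higher and 1 lower adjusted over the list alone, median 0.46, adjusted p = 0.00521, or 0.288 with an estimated correlation). Rises included the glutamate transporter gene Slc1a2 (3.34 ± 0.35), Clu (2.29 ± 0.34), Apoe (2.26 ± 0.67) and Sparcl1 (2.26 ± 0.27). Microglia markers rose for 4 of 25 and did not pass for 21 (6 higher adjusted over the list alone, median 0.64, adjusted p = 0.00521, or 0.636 with an estimated correlation). Rises included Cd68 (1.75 ± 0.32), Fcgr3 (1.5 ± 0.30), Aif1 (0.74 ± 0.19) and Lyz2 (0.56 ± 0.17, not past the test without CSMN P14 replicate 2). Cholesterol synthesis genes fell for 9 of 19, rose for 1 and did not pass for 9 (11 lower and 1 higher adjusted over the list alone, median -0.77, adjusted p = 7.78e-05, or 0.288 with an estimated correlation). Decreases included Cyp51 (-2.89 ± 0.48, but -1.84 without CSMN P14 replicate 2), Mvd (-2.40 ± 0.39), Fdps (-1.95 ± 0.42) and Idi1 (-1.80 ± 0.32). Young-neuron transcription factors fell for 7 of 23, rose for 1 and did not pass for 15 (8 lower and 2 higher adjusted over the list alone, median -0.39, adjusted p = 0.000598, or 0.246 with an estimated correlation), with Sox11 (-4.90 ± 0.22), Neurod6 (-2.85 ± 0.57) and Sox4 (-2.52 ± 0.29) lower and Cited2 (1.79 ± 0.49) higher. Without CSMN P14 replicate 2, Neurod6 was -1.63 and Cited2 2.78, and without replicate 1 Cited2 was 0.81.

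The largest rises in CSMN were those of the neuropeptide gene Cck (6.53 ± 0.34), Rasgrp1 (6.12 ± 0.23), Lamp5 (5.49 ± 0.31), Rasgrf1 (5.43 ± 0.30), Cracdl (5.25 ± 0.32) and the thyroid-hormone-responsive factor Klf9 (5.02 ± 0.30), besides Gabra4 and Egr1. The largest decreases besides Sox11 were those of Gprin2 (-4.39 ± 0.38), the matrix proteoglycan gene Vcan (-4.30 ± 0.20), Ermn (-4.21 ± 0.50), Masp1 (-4.17 ± 0.68), Trim67 (-4.16 ± 0.34), Gpr161 (-3.86 ± 0.37) and B3gnt5 (-3.72 ± 0.57, but -2.33 without CSMN P14 replicate 2).

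CSMN changed in 2751 genes between E18 and P14, 1687 higher and 1064 lower. Without CSMN P14 replicate 2 the count was 4563 (3018 higher, 1545 lower), with 2228 called in the same direction with both arrays. Without CSMN P14 replicate 1 it was 4970 and without CSMN E18 replicate 2 it was 1770. Of the lists, young-neuron factors (median -0.03), cholesterol synthesis (-0.56) and astrocyte markers (0.63) did not pass without CSMN P14 replicate 2, glutamate receptor and postsynaptic density genes (0.21) without replicate 1, and microglia markers without replicate 1 (0.08) or CSMN E18 replicate 1 (0.44). Medians of lists that still passed moved to 1.02 (glutamate), 1.44 (GABA), 1.59 (layer V), 1.09 (microglia) and 1.78 (early response) without CSMN P14 replicate 2, 0.20 (GABA) and 1.03 (corticospinal screens) without replicate 1, and 0.48 (oxidative phosphorylation) and 0.30 (astrocyte) without CSMN E18 replicate 2. Against P3, 2295 genes passed, 810 higher and 1485 lower, 1168 of them in the same direction as against E18. In that comparison the median was 0.77 for presynaptic genes, 0.70 for sodium, potassium and HCN channels, 0.05 for glutamate receptor genes, -0.15 for GABA receptor genes and 0.16 for oxidative phosphorylation, of which no gene passed in limma. The last 3 lists, the corticospinal screens (median -0.000532) and astrocyte markers (0.21) did not pass there. Of 69 genes named, 17 did not pass either: Apoe, Atp5d, Cacna2d3, Chst8, Cited2, Clu, Crym, Ddn, Egr3, Fcgr3, Gabra2, Gabrb1, Ndufa5, Ndufs3, Nrgn, Sparcl1 and Uqcrq.

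CPN and CSMN shared 979 genes that rose and 386 that fell between E18 and P14, against 172 and 95.5 expected for independent sets. Taking the mean of both types, 2377 genes differed between E18 and P3 (1666 higher at P3), 12 between P3 and P6 (11 higher at P6, 704 at an unadjusted p under 0.05) and 2342 between P6 and P14 (1003 higher at P14). The P3 against E18 count was 1578 without CPN E18 replicate 2, 1460 and 1262 without CPN P3 replicates 1 and 2, and 4172 without either CSMN P14 array. The P14 against P6 count was 1454 without CPN P14 replicate 1, 1466 and 1339 without CSMN P6 replicates 1 and 2, and 7318 without CSMN P14 replicate 1. The P6 against P3 count was 21 without either CPN E18 array, 2 and 5 without CPN P3 replicates 1 and 2, 3 without CPN P6 replicate 1, 7, 5 and 7 without CSMN P3 replicates 1, 2 and 3, 2 and 5 without CSMN P6 replicates 1 and 2, and 36 without either CSMN P14 array. The share higher at the later stage was 70.1% for P3 against E18, with 58.8% after quantile normalization and 57.7% after cyclic loess, and 91.7% for P6 against P3, with 81.2% after quantile normalization.

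Whether the 2 types aged differently was tested as the interaction, the change from E18 to P14 in CSMN minus that in CPN. It was led by transcripts that fell in CPN, where they were high at E18, and fell less or not at all in CSMN. Fabp7 (7.07 ± 1.02), Sox2 (6.47 ± 1.04), the growth factor gene Ccn2 (6.13 ± 0.76), Top2a (6.06 ± 0.41) and Neurog2 (5.71 ± 0.26) had large positive interactions, as did Pbx3 (7.02 ± 0.90). The metallothionein gene Mt1 (6.27 ± 0.69) had one of -0.06 through the probe set left without those marked for cross-hybridization. Cell cycle genes were positive for 18 of 27, negative for 1 and not past the test for 8 (23 and 1 adjusted over the list alone, median 2.38, adjusted p = 1.10e-28), also with Mki67 (5.41 ± 0.34), Cenpa (4.40 ± 0.37) and Cdk1 (4.07 ± 0.40). Progenitor genes were positive for 14 of 19 and not past the test for 5 (14 adjusted over the list alone, median 2.62, adjusted p = 1.00e-20), also with Eomes (5.48 ± 0.28) and Notch1 (4.91 ± 0.35). Astrocyte markers were positive for 10 of 20 and not past the test for 10 (13 positive and 1 negative adjusted over the list alone, median 1.85, adjusted p = 5.44e-10, or 0.0551 with an estimated correlation). Positive members included Gja1 (5.63 ± 1.03), Apoe (5.60 ± 0.95), Aldoc (5.13 ± 0.72) and Mlc1 (5.12 ± 0.48).

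Microglia markers had a positive interaction for 7 of 25 and did not pass for 18 (14 adjusted over the list alone, median 1.60, adjusted p = 1.37e-08, or 0.362 with an estimated correlation). Positive members included Ctss (3.94 ± 1.01), C1qa (3.77 ± 0.97, but 2.46 without CSMN P14 replicate 1), Fcgr3 (2.64 ± 0.43) and Ly86 (2.55 ± 0.59). Young-neuron transcription factors had one for 9 of 23 and did not pass for 14 (9 positive and 1 negative adjusted over the list alone, median 0.56, adjusted p = 1.52e-05, or 0.301 with an estimated correlation), with Insm1 (4.57 ± 0.62), Nfia (3.55 ± 0.31) and Zbtb20 (3.42 ± 0.40) besides Neurog2. This list's median was 1.08 without CSMN P14 replicate 2 and 0.86 without CPN E18 replicate 1. Calcium-binding and calcium-signalling genes leaned negative, with 1 of 30 past the test, Ryr2 (-2.14 ± 0.34), and 29 not (4 negative adjusted over the list alone, median -0.58, adjusted p = 0.00411, or 0.33 with an estimated correlation). The list did not pass without CSMN P14 replicate 2 (median -0.34). The largest negative interactions were those of Ermn (-4.36 ± 0.70), Frzb (-4.09 ± 0.53), Npy5r (-4.07 ± 0.76), Kcnv1 (-3.84 ± 0.46) and Gpr6 (-3.83 ± 0.55).

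The interaction passed for 943 genes, 643 positive and 300 negative, and its positive share of 68.2% was 53.5% after quantile normalization. With P3 in place of E18 it passed for 21 genes, 3 positive and 18 negative, all 21 called in the same direction against E18. Of 29 genes named, Ermn (-3.96) and Gpr6 (-3.16) passed there and the others did not, and Eomes (-0.43), Insm1 (-0.78) and Neurog2 (-0.27) changed sign. The young-neuron factor (median 0.17) and calcium (-0.19) lists did not pass there. The cell cycle (0.26, adjusted p = 0.0118), progenitor (0.51, adjusted p = 0.00887), astrocyte (0.36, adjusted p = 0.0118) and microglia (1.16, adjusted p = 2.37e-11) lists did, with 0, 0, 0 and 1 of their genes past the test in limma, and had an adjusted p of 0.457, 0.587, 0.616 and 0.457 with an estimated correlation. The count was 578 and 453 without CPN P14 replicates 1 and 2, 3597 without CSMN P14 replicate 1 and 1767 (1309 positive) without replicate 2.

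The last question was how corticotectal neurons compare with CSMN, which also project below the cortex, and with CPN. CTPN differed from CSMN at P14 in 35 genes, 25 higher and 10 lower, but in 0 with array weights or with a model of the groups compared alone (limma, 1602 at an unadjusted p under 0.05 with equal weights). Guidance receptors that were low in CSMN were among those higher in CTPN, namely Dcc (2.71 ± 0.37, adjusted p = 0.00778) and Unc5d (1.98 ± 0.29). The other largest increases were in Pbx3 (3.55 ± 0.64), Abca8a (3.02 ± 0.52), Spock3 (2.84 ± 0.33), Stxbp6 (2.74 ± 0.43), Car8 (2.63 ± 0.49), the nuclear receptor gene Rora (2.43 ± 0.34) and Tshz3 (2.35 ± 0.34). Those lower in CTPN were led by Cdc25c (-2.53 ± 0.42), the growth factor binding protein gene Igfbp4 (-2.46 ± 0.20, adjusted p = 7.59e-05), Tmtc1 (-2.34 ± 0.43), the formin gene Diaph3 (-2.22 ± 0.26), Slc35f4 (-1.96 ± 0.36), Nell1 (-1.93 ± 0.32), Tigar (-1.32 ± 0.25) and Susd2 (-1.23 ± 0.20). Without CSMN P14 replicate 2, Abca8a (1.94), Stxbp6 (2.24), Car8 (1.86), Cdc25c (-2.40) and Slc35f4 (-1.997) did not pass, and Pbx3 passed at 2.05. Cdc25c was -1.65 without CTPN P14 replicate 2. Of 18 named genes past the test, Tenm3 included, 12 and 15 did not pass without CTPN P14 replicates 1 and 2, and 7 without either CPN P14 array. Igfbp4, Diaph3 and Spock3 passed with each array left out in turn.

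The 5 genes that are named in every comparison of types did not pass between CTPN and CSMN: Bcl11b (0.29 ± 0.42, adjusted p = 0.84), Fezf2 (0.92 ± 0.28, adjusted p = 0.356), Crym (0.17 ± 0.47), Cux2 (0.52 ± 0.69) and Lmo4 (0.27 ± 0.33). Fezf2 passed without CSMN P14 replicate 1 (1.31) and was 0.54 without replicate 2. The last 3 were of either sign: Crym was -0.09 without CSMN P14 replicate 2, Cux2 -0.15 without CTPN P14 replicate 2 and -0.09 with the mean of its probe sets, and Lmo4 -0.04 without CTPN P14 replicate 1. Of the genes of the corticospinal screens, 2 of 15 were lower, Igfbp4 and Diaph3, and 13 did not pass (2 higher and 4 lower adjusted over the list alone, which is not independent evidence). Their median was 0.07, their mean -0.28, and the list did not pass (adjusted p = 0.161), except without CSMN P14 replicate 2 (median -0.11).

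Area patterning genes leaned higher in CTPN, with Tenm3 (2.31 ± 0.30) past the test and 17 of 18 not (2 higher adjusted over the list alone, median 0.31, adjusted p = 0.0213, or 0.605 with an estimated correlation). Axon growth and guidance genes were higher for 2 of 48, Dcc and Unc5d, and not past the test for 46 (5 higher adjusted over the list alone, median 0.17, adjusted p = 0.0323, or 0.605 with an estimated correlation). None of 32 glutamate receptor and postsynaptic density genes passed in limma (1 higher adjusted over the list alone, median 0.26, adjusted p = 0.0361, or 0.605 with an estimated correlation). None of 25 microglia markers passed (4 lower adjusted over the list alone, median -0.65, adjusted p = 4.50e-08, or 0.605 with an estimated correlation). These 4 lists rested on single arrays. Without CSMN P14 replicate 2 the area median was 0.14, the axon median -0.14 and the glutamate median -0.06, and none of these 3 passed. Area patterning did not pass without CSMN P14 replicate 1 (0.49) or CTPN P14 replicate 2 (0.23), nor axon growth (0.20) and glutamate receptor genes (0.06) without CTPN P14 replicate 2, nor microglia markers without CSMN P14 replicate 1 (-0.07). The axon and glutamate medians were 0.55 and 0.59 without CSMN P14 replicate 1, the glutamate median 0.47 without CTPN P14 replicate 1 and the microglia median -1.18 without CSMN P14 replicate 2.

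The count of 35 between CTPN and CSMN was 22 without either CPN P3 array, 20 without either CPN P14 array, 23 without CSMN P3 replicate 2 or 3, 21 without either CSMN P6 array, 5143 and 65 without CSMN P14 replicates 1 and 2, and 17 and 12 without CTPN P14 replicates 1 and 2. Of the 65 without CSMN P14 replicate 2, 17 were higher in CTPN and 48 lower, and 21 were also called, in the same direction, with both arrays. The share higher in CTPN was 71.4%, and 55.8% after cyclic loess.

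Against CPN, some subcerebral genes were higher in CTPN. Bcl11b was 8.70-fold higher (3.12 ± 0.42, adjusted p = 0.00131), Fezf2 6.89-fold (2.79 ± 0.28, adjusted p = 0.000218), Crym 8.82-fold (3.14 ± 0.47, adjusted p = 0.00335), and Npr3 was higher by 3.68 ± 0.41. Lmo4 was 3.11-fold lower (-1.64 ± 0.33, adjusted p = 0.0271), and Cux2 had a difference of -2.86 ± 0.69 (adjusted p = 0.0691). Pbx3 (4.96 ± 0.64), Abca8a (3.26 ± 0.52), Gprc5b (2.96 ± 0.42), the peptide receptor gene Qrfpr (2.90 ± 0.63) and Vat1l (2.79 ± 0.38) completed the largest increases. The largest decreases were in S100a6 (-3.81 ± 0.41), Tnnc1 (-3.42 ± 0.30), Prdm8 (-3.13 ± 0.52), Egr2 (-3.09 ± 0.49), Neurod6 (-2.85 ± 0.57), Lmcd1 (-2.79 ± 0.28) and the glutamate transporter gene Slc17a6 (-2.74 ± 0.40). Trbv1 (-3.65 ± 0.42) had a difference of 0.04 through the probe set left without those marked for cross-hybridization.

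Of the corticospinal screen genes, 7 of 15 were higher in CTPN than in CPN, including Bcl11b, Crym and Fezf2, 1 was lower (Igfbp4, -2.37 ± 0.20) and 7 did not pass (9 higher and 2 lower adjusted over the list alone, which is not independent evidence, median 1.29, adjusted p = 3.06e-10). Of the callosal screen genes 6 of 17 were lower, including Nectin3 (-2.50 ± 0.47, but -1.53 without CTPN P14 replicate 1), Plxnd1 (-2.44 ± 0.33), Chn2 (-2.04 ± 0.46) and Hspb3 (-1.86 ± 0.35), and 11 did not pass (9 lower adjusted over the list alone, which is not independent evidence, median -1.32, adjusted p = 1.03e-16). Layer V and subcerebral markers were higher for 7 of 17, with Tox (2.14 ± 0.28) and Parm1 (2.00 ± 0.44) besides Npr3 and Vat1l, and not past the test for 10 (12 higher adjusted over the list alone, median 1.49, adjusted p = 4.48e-20). Upper-layer markers were lower for 2 of 18, Stard8 (-2.21 ± 0.25) and Cdh10 (-1.78 ± 0.27), and not past the test for 16 (11 lower and 1 higher adjusted over the list alone, median -1.21, adjusted p = 2.28e-11). Axon growth and guidance genes were higher for 3 of 48, Nrp1 (1.75 ± 0.29), Epha5 (1.53 ± 0.33) and Tubb2b (1.45 ± 0.29), and not past the test for 45 (15 higher and 4 lower adjusted over the list alone, median 0.31, adjusted p = 1.29e-06, or 0.617 with an estimated correlation).

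Early response and stress genes were lower for Egr2, higher for Gadd45b (1.16 ± 0.23) and not past the test for 25 of 27 (6 lower and 1 higher adjusted over the list alone, median -0.18, adjusted p = 0.00378, or 0.617 with an estimated correlation). None of 18 interneuron markers passed in limma over all genes or over the list alone (median -0.41, adjusted p = 0.00375, or 0.617 with an estimated correlation). Without CTPN P14 replicate 1 neither of these lists passed (medians -0.20 and -0.19), and without replicate 2 the early response median was -0.11 and the axon growth median 0.48. CTPN differed from CPN in 193 genes, 83 higher and 110 lower. Of 31 named genes past the test, 14 and 16 did not pass without CPN P14 replicates 1 and 2, and 11 and 9 without CTPN P14 replicates 1 and 2. The count was 51 and 65 without CPN P14 replicates 1 and 2, 395 without either CSMN P14 array and 101 without CTPN P14 replicate 2.

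At P14, CSMN and CTPN shared 28 genes higher and 75 lower than in CPN, against 0.37 and 1.04 expected for independent sets. Both comparisons use the same 2 CPN P14 arrays, so they correlate by construction. Across genes (not independent replicates) r was 0.596, against 0.501 in simulations with no difference, and the covariance 0.118 against 0.0487. The 100 simulations shared 0 calls, but with no difference to call 0 is uninformative. The 103 shared genes were 2 with array weights, 0 with a model of the groups compared alone, 20 and 35 without CPN P14 replicates 1 and 2, 228 and 162 without CSMN P14 replicates 1 and 2, and 65 and 64 without CTPN P14 replicates 1 and 2.

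One array stood apart from the rest of the series. CSMN P14 replicate 2 had a highest correlation of 0.922 with another array, against 0.949 to 0.996 for the others, and 0.904 with its own replicate. The difference between the 3' and 5' control probe sets of Gapdh was 3.08 in it and 1.39 to 2.78 in the others.

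**Figure D4:**
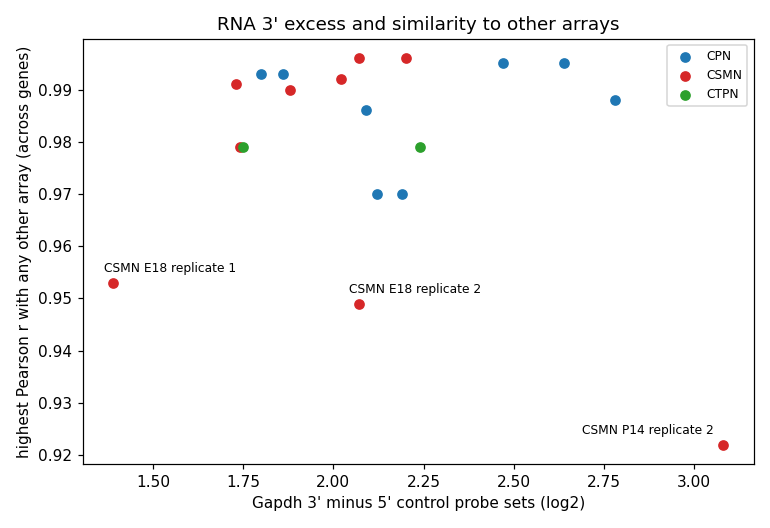
Difference between the 3' and 5' probe sets of Gapdh (log2, horizontal axis) against the highest correlation of each array with another array (vertical axis), with a circle per array (blue CPN, red CSMN, green CTPN). CSMN P14 replicate 2 lay at 3.08 and 0.922, apart from the others.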

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

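The 3 tests on the CPN E18 arrays and the 3 tests on CSMN P14 replicate 2 were chosen after the result was seen, and so were the interaction lists with P3 in place of E18 and the list medians beside the last split.

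The change from E18 to P14 differed between CSMN and CPN for 943 genes by the interaction test. Positive values, a change higher in CSMN, belonged to Fabp7 (7.07), Pbx3 (7.02), Sox2 (6.47), Mt1 (6.27), Ccn2 (6.13), Top2a (6.06), Neurog2 (5.71), Gja1 (5.63), Apoe (5.60), Eomes (5.48), Mki67 (5.41), Aldoc (5.13), Mlc1 (5.12), Notch1 (4.91), Insm1 (4.57), Cenpa (4.40), Cdk1 (4.07), Ctss (3.94), C1qa (3.77), Nfia (3.55), Zbtb20 (3.42), Fcgr3 (2.64) and Ly86 (2.55). Negative values belonged to Ermn (-4.36), Frzb (-4.09), Npy5r (-4.07), Kcnv1 (-3.84), Gpr6 (-3.83) and Ryr2 (-2.14). By list, the interaction medians past the test with the preset correlation were 2.62 for progenitors, 2.38 for cell cycle, 1.85 for astrocytes, 1.60 for microglia and macrophages, 0.66 for area patterning, 0.56 for young-neuron transcription factors, 0.33 for axon growth and guidance, 0.31 for the corticospinal screens, -0.58 for calcium genes, -0.47 for glutamate receptor and postsynaptic density genes, -0.39 for presynaptic genes, -0.38 for sodium, potassium and HCN channels and -0.37 for cholesterol synthesis. With an estimated correlation the cell cycle (adjusted p = 0.000117) and progenitor (0.00257) lists passed. The others did not: 0.0551 for astrocytes, 0.301 for area patterning and for young-neuron factors, 0.33 for calcium genes, 0.362 for microglia and macrophages, 0.428 for the corticospinal screens, 0.731 each for presynaptic, glutamate receptor and channel genes, and 0.748 each for axon growth and cholesterol synthesis. With P3 in place of E18, microglia and macrophages (1.16), progenitors (0.51), astrocytes (0.36), cell cycle (0.26) and axon growth (0.18) passed with the preset correlation, and none of the 13 lists did with an estimated one (lowest adjusted p = 0.457). Area patterning (0.21, adjusted p = 0.276), young-neuron factors (0.17, 0.253), the corticospinal screens (-0.06, 0.971), calcium (-0.19, 0.375), glutamate receptor (-0.22, 0.419), presynaptic (-0.05, 0.902), channel (-0.07, 0.902) and cholesterol (-0.36, 0.193) genes did not pass there.

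Single arrays ended some of these list calls at the preset correlation. Without CSMN P14 replicate 2 the presynaptic (median -0.16), glutamate receptor (-0.04), channel (0.10), calcium (-0.34) and cholesterol (-0.10) lists did not pass, and without replicate 1 the corticospinal screens (0.10), area patterning (0.36) and axon growth (-0.10) did not. Without CSMN E18 replicate 1 this held for area patterning (0.76), presynaptic (-0.32), glutamate receptor (-0.20), channel (-0.37) and cholesterol (-0.44) genes, and without CSMN E18 replicate 2 for the corticospinal screens (0.35) and axon growth (0.06). Without CPN E18 replicate 1 it held for the corticospinal screens (0.35), area patterning (0.47), axon growth (0.21) and channels (-0.32), and without CPN E18 replicate 2 for presynaptic (-0.39), glutamate receptor (-0.40) and cholesterol (-0.28) genes. Without CPN P14 replicate 1 it held for cholesterol synthesis (-0.39), without CPN P14 replicate 2 for the corticospinal screens (0.30), glutamate receptor (-0.40) and channel (-0.39) genes, and without either CTPN P14 array for glutamate receptor (-0.47) and channel (-0.38) genes.

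Among 10092 probe sets without a single gene symbol, which no comparison of genes uses, 141 differed between CSMN and CPN in the mean of 4 stages, 30 higher and 111 lower in CSMN.

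Cell cycle and progenitor transcripts were higher in the CPN E18 arrays than in CSMN at E18, and with P3 in place of E18 the interaction passed for 21 genes. A lower share of neurons that raises every other cell type alike stays open. The median difference over oligodendrocyte, vascular and interneuron markers was -0.0601 (-0.171 to 0.1 over 4 pairs of arrays), but these lists were dim in CPN at E18 (medians 6.54 to 7.5). The progenitor difference was 2.78 (lowest pair 2.36). Astrocyte markers rose by 1.93 (1.37 to 2.3) and microglia markers by 0.694 (0.312 to 1.21), and RNA of these cells beside neurons stays open. RNA of dividing progenitors and radial glia in the sorted CPN sample may account for it: 82.6% of the 46 measured members of both lists were highest in both CPN E18 arrays, against 6.87% of all genes, and abundant radial glial genes stood high in both (Fabp7 at 13.8 and 13.7, Vim at 13.3 and 13.1, Slc1a3 at 11.8 and 11.9). This is modest evidence, since the same lists define the pattern, 1 of the 46 is also on another list, glia express Vim and Fabp7 too, and sorting for microspheres would remove unlabelled cells. Younger callosal neurons that still hold these transcripts stay open, since the young-neuron list was higher by 0.371, and the biological difference between the types at E18 stays open as well, untested.

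CSMN P14 replicate 2 stood apart from the other arrays. A callosal sample under the wrong label was argued against: over 97 genes that separated the types at P3 and P6 it lay at 0.719 (95% interval 0.599 to 0.837 from 1000 resamplings of the genes) between the CPN P14 mean at 0 and the other CSMN P14 array at 1, while the CTPN arrays lay at 0.735 and 0.627. A corticotectal sample under the wrong label stays open. Over the 65 genes called between CTPN and CSMN without this array it lay at 0.493 (95% interval 0.351 to 0.654) between the CTPN mean at 0 and the other CSMN P14 array at 1, with the CPN P14 arrays at 0.406 and 0.392. Among these genes Igfbp4 (12.4), Diaph3 (8.45) and Dcc (4.60) lay nearer the other CSMN P14 array (12.6, 7.98 and 5.94) than both CTPN arrays (9.998 and 10.09, 6.32 and 5.66, and 8.05 and 7.93), but the set as a whole did not. RNA quality or amplification may account for it, with a 3' minus 5' difference of Gapdh of 3.08 (1.39 to 2.78 in the others) and of actin of 2.16 (0.582 to 1.48). The microglial genes Csf1r (11.3 and 9.13) and C1qa (9.73 and 7.10) also differed between CSMN P14 replicates 1 and 2. No biological explanation was tested, since both arrays share 1 group.

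Chance was tested with other splits of the arrays for the comparisons that have at least 3 arrays a side. These fits carry stage or type as a covariate, so their real values differ from the counts of the report, and splits by type were left out for the stage steps. For CSMN against CPN the real split gave 736 genes and the highest other split 78, and 1 of 100 splits gave as many, so chance can be excluded. For P3 against E18 the values were 1873 and 93 (1 of 99 splits), and for P14 against P6 1074 and 305 (1 of 34), so chance can be excluded there too. For P6 against P3 the real split gave 88 genes and 2 of 99 splits gave as many. That share is also under 0.05. The highest other split gave 679, so chance is not excluded and the count does not tie these genes to the stage. That split put both CPN P3 arrays, CPN P6 replicate 2 and CSMN P3 replicate 3 on 1 side, and a count that far above the real one points to a structure of the samples. The 4 arrays lay apart from the 5 others of P3 and P6 in the median of interneuron markers (6.48 to 6.93 against 5.81 to 6.10), vascular markers (7.19 to 7.75 against 6.73 to 7.10), glycolysis genes (10.6 to 10.8 against 11.1 to 11.3) and motor neuron disease genes (10.15 to 10.36 against 10.57 to 10.73), and overlapped in the 26 other lists.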

How the results depend on the processing

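Leaving the E18 arrays out of a comparison was chosen after the result was seen, and so was the count of genes shared by ageing CPN and CSMN; the other alternatives were planned.

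Most values kept their direction and their side of the threshold. Of 326 values of named genes, 1 call ended and 1 was added under quantile normalization, 2 ended under cyclic loess and 3 with an intensity trend. Calls ended for 72 values with array weights (2 added), 60 with a model of the groups compared alone (1 added), 16 with the mean of all probe sets, 9 of 320 without probe sets marked for cross-hybridization (3 of them with a changed sign) and 1 among the genes above the median brightness (1 added). Of the 218 values that have a setting without E18, 78 ended, 7 of them with a changed sign. Of 60 list values, 9 ended among the brighter genes, 3 each with loess and quantile normalization, and 1 with the mean of probe sets. Of the 48 that have a setting without E18, 13 ended, 2 of them with a changed direction of the list test. Filters removed 79 gene values (brightness) and 6 (cross-hybridization), so these have no value there. Of 317 gene values past the test, 71 were no longer past it without at least 1 array. The deposited values carry no detection calls, so signal of dim genes could not be told from background. A group left with 1 array is assumed to vary like the other groups.

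A minimum absolute log2 difference of 1 gave 373 genes for CSMN against CPN over 4 stages, 1005 for P3 against E18 and 1163 for P14 against P6, by construction fewer. The genes above the median brightness, also fewer by construction, gave 1330 at E18, 147 at P14, 349 for the interaction, 19 for CTPN against CSMN, 119 for CTPN against CPN and 60 for the genes shared by both comparisons with CPN at P14. Cyclic loess gave 262 at P3, 29 for P6 against P3 and 33 at all 4 stages. Quantile normalization gave 1459 for the interaction and 34 at all 4 stages. The cause was not tested for these normalizations.

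Array weights gave 992 at E18, 3176 at P3, 875 at P6, 2 at P14, 259 for CSMN P14 against E18, 184 for the interaction, 389 for P6 against P3, 1419 for P14 against P6, 0 for CTPN against CSMN (limma; 1602 at an unadjusted p under 0.05 with equal weights), 588 for CTPN against CPN, 0 at all 4 stages, 2 shared with CPN at P14 and 233 shared in ageing. Both arrays of a group of 2 get the same weight by construction (0.143 each for CSMN P14), so the weights act on groups. A model of the groups compared alone gave 843 at E18, 819 at P3, 68 at P6, 0 at P14 (limma; 2602 at an unadjusted p under 0.05 with all arrays), 344 for CSMN P14 against E18, 152 for the interaction, 69 for P6 against P3, 1046 for P14 against P6, 0 for CTPN against CSMN, 359 for CTPN against CPN, 0 at all 4 stages, 0 shared with CPN at P14 and 292 shared in ageing. Its spread uses fewer arrays, but some counts rose, as at P3.

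Without E18 the counts were 747 over 4 stages, 1480 for CPN, 2295 for CSMN, 21 for the interaction and 835 shared in ageing. Signs changed for Mki67 (0.10) and Top2a (0.28) over 4 stages, Eomes (0.23) in CPN, Gabra2 (-0.15) in CSMN, and Eomes (-0.43), Insm1 (-0.78) and Neurog2 (-0.27) in the interaction, and for the cell cycle (0.0831) and astrocyte (0.0929) lists over 4 stages. The other list calls that ended, among those described, were those of progenitors (-0.0865) and early response genes (-0.184) over 4 stages, glutamate receptor genes (0.287) and astrocytes (-0.134) in CPN, glutamate receptor (0.0509), GABA receptor (-0.152, from 0.901), oxidative phosphorylation (0.16), corticospinal screen (-0.000532, from 1.55) and astrocyte (0.206) genes in CSMN, and young-neuron factors (0.17) and calcium genes (-0.193) in the interaction. Signs also changed without probe sets marked for cross-hybridization for Uqcrq (-0.0544, CSMN), Mt1 (-0.0571, interaction) and Trbv1 (0.0391, CTPN against CPN), where another probe set stood for the gene, and with the mean of all probe sets for Cux2 (-0.0914, CTPN against CSMN). The cause was not tested beyond this.

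With each array left out in turn, counts ran from 1038 to 5262 over 4 stages, 1121 to 4253 at E18, 29 to 341 at P3, 53 to 383 at P6, 40 to 6256 at P14, 2137 to 4582 for CPN ageing, 1770 to 4970 for CSMN ageing, 453 to 3597 for the interaction, 1262 to 4172 for P3 against E18, 2 to 36 for P6 against P3, 1339 to 7318 for P14 against P6, 12 to 5143 for CTPN against CSMN, 51 to 395 for CTPN against CPN, 7 to 45 at all 4 stages, 20 to 228 shared with CPN at P14 and 930 to 1912 shared in ageing. The highest of these gene counts came without CSMN P14 replicate 1, except that shared in ageing (without replicate 2). The lists past the test ran from 66 (without CSMN P14 replicate 1) to 75 (without CPN P6 replicate 1), against 70. Between CTPN and CSMN, Crym ran from -0.0874 to 0.417, Cux2 from -0.148 to 1.20 and Lmo4 from -0.0401 to 0.581, the axon growth median from -0.138 to 0.545 and the glutamate receptor median from -0.0607 to 0.585. The axon growth median over 4 stages ran from -0.0485 to 0.14. Beyond the shared spread no cause was tested.

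A replicate block moved no count by more than 1.5 times (1576 over 4 stages, 2617 at E18, 216 at P3, 218 at P6, 265 at P14, 3777 for CPN ageing, 3046 for CSMN ageing, 977 for the interaction and 26 for CTPN against CSMN), ended 5 gene calls and 1 list call and added 3 gene calls. The replicate numbers are not known to pair arrays: over the 28 pairs of the 8 groups of 2, the differences between replicates 1 and 2 correlated by -0.222 to 0.593 (median 0.0813), above 0.1 in 13 pairs.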

Other observations

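The test of the corticotectal hypothesis was planned before its value was seen, but reading a tie as undecided was set after.

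Layer VI and subplate genes went both ways between CSMN and CPN in the mean of 4 stages. Foxp2 was higher in CSMN (1.39 ± 0.15), Nr4a2 (-1.54 ± 0.30), Tbr1 (-1.09 ± 0.28), Moxd1 (-0.73 ± 0.17) and Ntsr1 (-0.66 ± 0.15) were lower, and 11 of 16 did not pass (1 higher and 4 lower adjusted over the list alone; median -0.01; adjusted p = 0.208). Of 12 striatal markers Foxp2 was higher, Gpr6 (-1.90 ± 0.19) and Isl1 (-0.36 ± 0.10) lower and 9 not past the test (2 higher and 3 lower adjusted over the list alone; median 0.06, mean -0.06; adjusted p = 0.862). Of 24 motor neuron disease genes, Atl1 (0.50 ± 0.12) and Pfn1 (0.43 ± 0.12) were higher in CSMN and 22 did not pass (2 higher adjusted over the list alone; median 0.07; adjusted p = 0.787).

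In this comparison, of 21 oligodendrocyte genes Ermn was higher, Olig1 (-1.74 ± 0.34) and Pdgfra (-0.83 ± 0.23) lower (0 without E18) and 18 did not pass (1 higher and 3 lower adjusted over the list alone; median 0.06, mean 0.11, test leaning down; adjusted p = 0.979). Of 22 vascular genes Slco1c1 (-1.65 ± 0.19), Cldn5 (-0.98 ± 0.23) and Sparc (-0.95 ± 0.26) were lower (0 without E18) and 19 did not pass (3 lower adjusted over the list alone; median -0.05; adjusted p = 0.142). None of 8 erythroid and choroid plexus genes passed in limma over all genes or the list (median 0.08; adjusted p = 0.972). Of 4 sex-linked genes Xist was lower (-1.35 ± 0.27) and 3 did not pass (1 lower adjusted over the list alone; median -0.09; adjusted p = 0.671).

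A hypothesis was that CTPN share part of the callosal profile that CSMN lack, so that genes higher in CTPN than in CSMN at P14 would be higher in CPN at P3 and P6. Of 25 such genes 15 were higher in CPN in the mean of P3 and P6 (median difference 0.13), and 6 were called higher at P3 or P6. Random genes of like expression gave a median of 10 and an upper bound of 15, which the count equalled, so the test does not decide it.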
